A study of Vitis vinifera with 204 samples.

How the data were processed

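Gene expression was measured by RNA-seq in libraries of berry pericarp, 3 for each of 68 cells of season, time point and thinning intensity. Per the series design, vines stood in randomized blocks of 6 along 9 rows, with 3 rows per treatment. From each block 26 clusters were collected. Seeds were taken out during grinding, so the tissue is pericarp. Libraries were not strand-specific and were made from 2.5 µg of total RNA, per the labels' protocols. The protocols speak of 206 libraries, of which the 3 in each of the 68 cells were analysed here. Season and replicate number were taken from the sample titles and source names. A separate year tag in the labels differs from the season for 134 samples and goes with it for 70, while the day after veraison goes with the title, so the tag was used only in an alternative.

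The deposited table holds RPKM values, which the authors computed from the reads. TopHat2 2.0.6 and Cufflinks 2.0.2 were used, per the submitters' processing notes; their settings, the genome build and the annotation are not given in the sources used here. No counts were used, and every library lists values above 0 and under 0.01 RPKM. Whole reads were not recovered, so the depth per library is unknown. No interval or floor from counting was therefore computed. Reads from a gene and an overlapping antisense gene cannot be told apart in libraries without strand, and how reads shared between near-identical genes were assigned is not given in the sources used here. Every column of the table was matched to a sample by its title, and no other column of values was left over.

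An exact 0 can be a failed estimate in this table. In 312 genes at least 1 library is listed at 0 while both other replicates of its cell hold at least 5 RPKM. Each library has between 1 and 47 such values, with a median of 6. Genes with such a value were kept in the tests and left out in an alternative.

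Genes with at least 1 RPKM in at least 3 libraries were kept. Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend of the prior variance, Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale and understate the change of genes near 1 RPKM. Thinning was tested with the 34 season time points as a factor and 1 thinning coefficient per season, and the mean of the 3 coefficients was the main comparison. Stage comparisons used a mean for each of the 68 cells with equal weight on both arms, and for ripening onset, late ripening, harvest and intervals a change of at least 2-fold was also required. The designs, the gene lists and a first set of alternatives were written before the data were examined.

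A library was taken to hold the second form of RPKM values when at least 20 of the 9114 steadily expressed genes were listed under 0.5 RPKM; libraries of the first form had at most 14, and the next highest had 6. Second-form libraries also list fewer values above 0 and under 0.01 RPKM, with a median of 9 and at most 78, against a median of 205 in the first form. The ranges overlap in 1 library: replicate 2 of the 75% arm on day 74 of 2012, the first-form library with 14 such genes, lists 61, and the next lowest lists 135. The form was defined from the values, after seeing the data, and is not a group of the study. Its effect was estimated in the cell model, where only the cells of 2013 with both forms inform it. In these cells replicate 2 of the 75% arm held the second form, on days -20 and -6, both before veraison. It also had the highest ripening score (described below) of each cell. The score was -3.595 against -3.889 and -3.646 on day -20, and 2.224 against 1.826 and 0.445 on day -6. The estimated effect of the form was therefore not told apart from a difference in stage within these cells.

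Sugar content came from the labels. Differences between arms in sugar and in the ripening score were tested by permuting thinning labels within time points (two-sided, 100000 resamples, Python 3.11.15, numpy 2.4.6, scipy 1.17.1). Between-season differences were tested by the range of the 3 season means under the same permutations. The rule for named genes, for thinning and the ripening comparisons, took the 5 largest increases and 5 largest decreases past the threshold with the same direction in each season, at least 5 RPKM in the higher group and a gene name. No ID had a name, so at most 2 IDs that rose and 2 that fell are printed per comparison, without that condition and without genes that are form-dependent or hold an implausible 0; this last condition was chosen after seeing the data. The gene lists, the seed markers and the camera tests gave no value for the same reason.

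The fits were tested on simulated data with the real gene means, cell means and spread of the 20770 genes, drawn from a normal distribution. For the mean thinning difference 84% of the 50 genes changed 1.1-fold and all of the 50 changed 1.25-fold were called, with 9 false calls. At a single time point, 3 against 3, 26% of the 50 genes changed 1.25-fold and 90% of the 50 changed 2-fold were called. These shares hold for the chosen genes and the simulated spread only. For thinning in 2012 the simulation gave 9 false calls, while the highest other split of the real libraries gave 3286 genes. The simulated false calls therefore do not carry over to the real libraries. Alternatives covered the pseudocount (0.1), the filter, median ratio scaling, quantile normalization, robust variance, replicate blocks, correlation within plots, means per replicate number, sugar and the form as covariates, separate fits per season, the year tag and each replicate left out. Thinning in 4 windows of development (before day 0, day 0, days 8 to 22, last 2 time points), the interval comparisons, the number of expressed genes, the spread between replicates, the shift in days and the correlations were added after seeing the data. For each count of genes, other splits of the libraries were drawn, 100 in all where that many exist.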

Results

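RNA was sequenced from the pericarp of Cabernet Sauvignon grape berries (Vitis vinifera) picked in a vineyard near Modesto, California. Cluster thinning, the removal of young clusters after fruit set so that fewer berries share the sugar made by the leaves, had taken away either 50% or 75% of the crop load. Unthinned vines were not analysed here. Berries were followed from the green stage through veraison, when grapes soften and colour, to harvest in 3 seasons. The 2012 season held 12 time points from day -28 to day 80 after veraison, 2013 held 10 from day -20 to day 43, and 2014 held 12 from day -14 to day 63. Each combination of season, time point and thinning intensity, called a cell, held 3 replicate libraries, with 102 libraries per thinning intensity. A sample was a pool of 60 berries out of 6 clusters, so p-values measure the spread between such pools. Per the series design each treatment had 3 rows, so the libraries of an intensity are repeated pools from these rows. The main tests do not take the rows as the replicates.

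The values were RPKM (read density scaled to gene length and library size) for 29971 gene IDs, of which 20770 passed the filter on low values. The RPKM of a library summed to between 817623 and 1105140, with a median of 925588; read depth is unknown. The files do not pair the IDs with gene names and 0 of the 29971 IDs matched the reference gene table, so the fixed gene lists and seed markers could not be applied and groups of genes are described by their course over ripening. No 2 libraries held identical values, and the highest Spearman correlation between any pair was 0.993.

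Berries went from almost no sugar to harvest levels along one main axis of expression. Sugar in the 50% thinned berries of 2012 was 0.50 g/100 ml ± 0.00 (SD, n = 3) on day -28, 7.07 ± 0.06 on day 0 and 24.2 ± 1.64 on day 53. The first principal component, which ran from green to ripe berries, held 57.1% of the variance of log2 values, and the second held 12.6%. A ripening score was computed per library as the mean log2 value of 200 genes that rose at the onset of ripening minus that of 200 genes that fell, both chosen in the other 2 seasons. In the 50% thinned berries of 2012 it climbed from -4.36 ± 0.05 (SD, n = 3) on day -28 to 2.73 ± 1.32 on day 0 and 5.96 ± 0.15 on day 42. Day 0 did not mark the same stage in each season: the 50% thinned berries held 2.43 g/100 ml ± 1.09 (SD, n = 3) of sugar on day 0 of 2014 against 8.20 ± 1.33 on day 0 of 2013, with scores of 0.06 ± 1.08 and 4.07 ± 0.15.

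**Figure D1:**
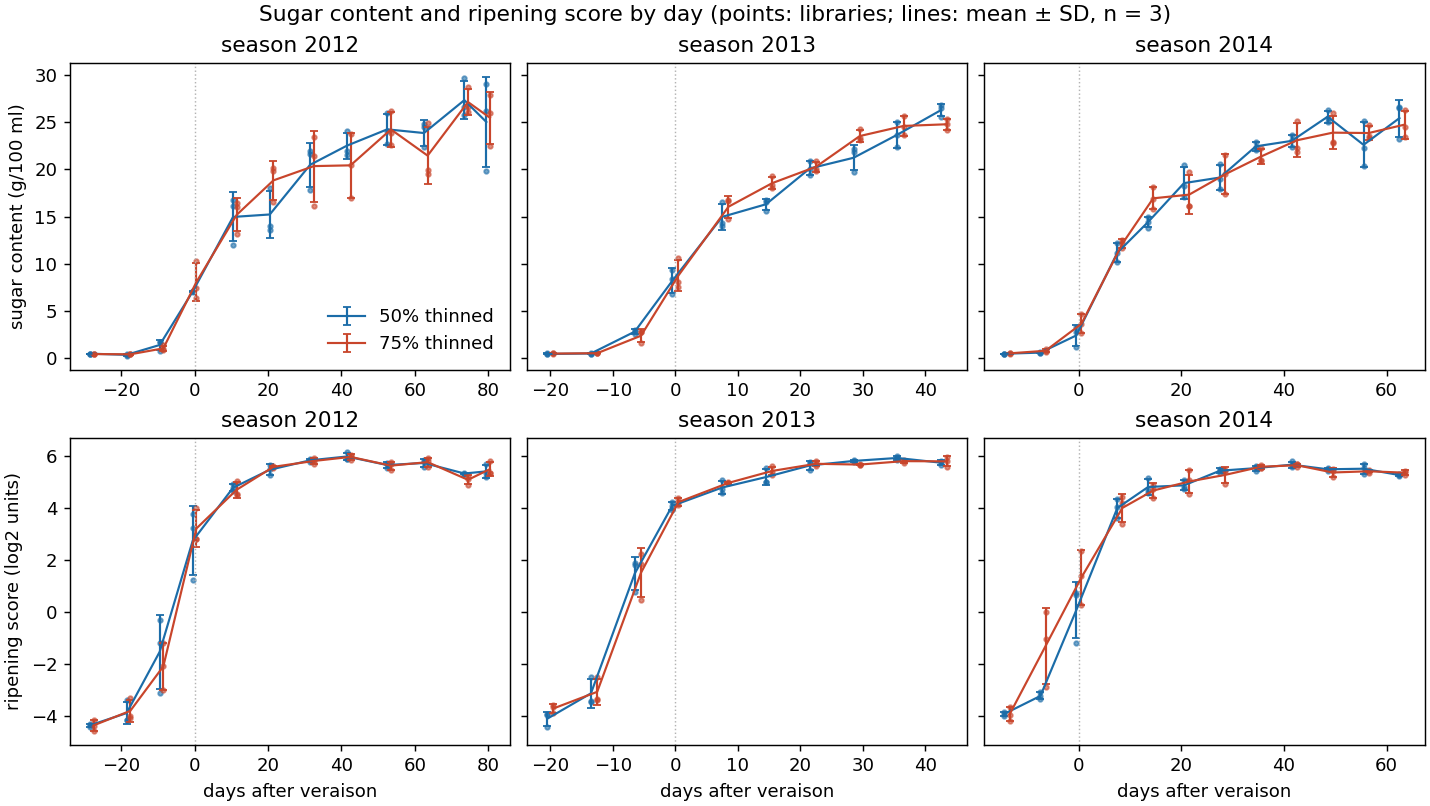
Sugar content (top row, g/100 ml) and ripening score (bottom row, log2 units) against days after veraison in the seasons 2012, 2013 and 2014, with libraries as points and lines and bars for the mean ± SD of 3 replicates at 50% and 75% thinning. The score climbed around veraison in every season, and the arms stood furthest apart on day -7 of 2014, at -3.23 ± 0.14 and -1.32 ± 1.45.

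From green berries to days 8 to 22 after veraison, the onset of ripening, 4654 genes changed at least 2-fold in limma, 22.4% of those tested. Of these, 945 rose and 3709 fell, and 292 rose and 1120 fell at least 4-fold. The median change was 1.5 on the log2 scale among genes that rose and -1.56 among genes that fell. Between years, 4634 of the 4654 genes, which were called on the mean of the seasons, moved in the same direction in all 3. Across genes, which are not independent replicates, the log2 changes of any pair of seasons had Pearson's r between 0.899 and 0.912. The gene VIT_12s0034g01970 rose from 20.8 RPKM ± 81.2 (SD, n = 48 libraries) in green berries to 1682 ± 682 (n = 48) in early ripening, a log2 change of 8.76 (SE 0.16, limma adjusted p = 2.43e-94). VIT_11s0016g04920 rose from 102 RPKM ± 268 to 6173 ± 2627. VIT_18s0122g00290 fell from 189 RPKM ± 79.0 to 0.472 ± 1.17, a log2 change of -7.00 (SE 0.10, limma adjusted p = 1.38e-106), and VIT_02s0154g00320 fell from 524 RPKM ± 813 to 0.593 ± 0.704. The balance of rising and falling genes depended on the scaling. As deposited, the median log2 change of all genes at onset was -0.24; it was -0.06 with median ratio scaling, which gave 1341 rising and 2937 falling genes, and 0.09 with quantile normalization, which gave 1708 and 2368.

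Late ripening, from days 8 to 22 to the last 2 time points of a season, changed 2901 genes at least 2-fold in limma, 14% of those tested. Here 1193 rose and 1708 fell, and 2862 of the 2901, also called on the mean of the seasons, moved the same way in all 3. Median ratio scaling gave 905 rising and 2000 falling genes. In 2013 the form of the RPKM values, described below, moved with this step. The libraries of days 8 to 22 held the first form, and 9 of the 12 libraries of the last 2 time points held the second. VIT_00s0301g00100 rose from 9.15 RPKM ± 8.15 (SD, n = 48) to 400 ± 242 (n = 36), and VIT_00s0270g00010 rose from 3.20 RPKM ± 3.99 to 138 ± 59.9. VIT_11s0016g05840 fell from 207 RPKM ± 87.5 to 1.74 ± 4.07, a log2 change of -6.59 (SE 0.15, limma adjusted p = 8.61e-82), and VIT_12s0059g00490 fell from 412 RPKM ± 194 to 9.20 ± 10.9.

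Among the 1193 genes that rose late, 898 had not passed the 2-fold threshold at onset, 176 had risen and 119 had fallen. Among the 1708 that fell late, 786 had not passed it at onset, 702 had already fallen and 220 had risen. Independent lists of these sizes would share 305 genes that fell at both steps, 54.3 that rose at both, 77.7 that rose and then fell and 213 that fell and then rose. Both comparisons share the libraries of days 8 to 22. In 20 simulations of unchanged genes with these libraries the overlap was 0 genes in each, a value that leaves out the real changes. In a test chosen after seeing the data, the libraries of days 8 to 22 were divided so that onset used those of 1 replicate number and late ripening the others. With replicate 1, 2 or 3 for onset, 678, 730 and 739 genes fell at both steps, 165, 184 and 180 rose at both, 219, 218 and 213 rose and then fell, and 117, 114 and 111 fell and then rose.

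In each season 1 interval around veraison held the most changed genes. In 2012 it was day -9 to day 0, with 663 genes rising and 2232 falling at least 2-fold. In 2013 it was day -13 to day -6, with 641 and 1835, and in 2014 day 0 to day 8, with 311 and 1653. After day 8 the intervals of 2013 and 2014 held between 34 and 601 changed genes. The 2012 season had a further burst between day 63 and day 74, with 759 genes rising and 750 falling. On day 74, replicate 1 of the 50% arm held 32 implausible 0 values and replicate 2 of the 75% arm held 38, against a median of 6 per library. No splits or leave-outs were run for this interval. Median ratio scaling gave 908 rising and 1569 falling genes in the leading interval of 2012, 707 and 1544 in that of 2013 and 543 and 1057 in that of 2014. Quantile normalization gave 1016 and 1359, 871 and 1323, and 559 and 863.

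**Figure D2:**
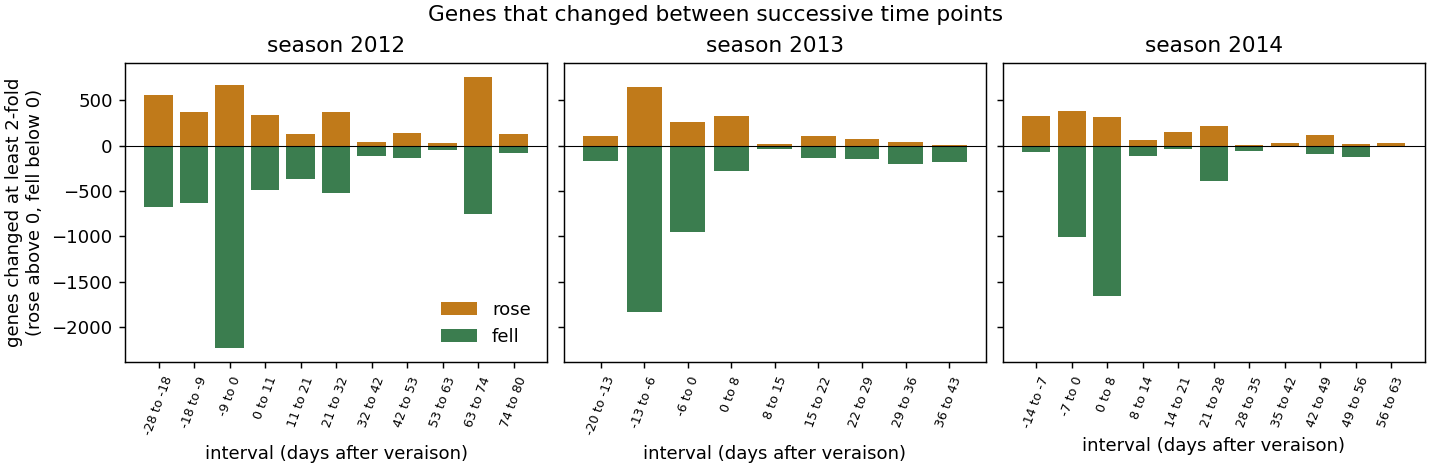
Genes that changed at least 2-fold (limma, adjusted p under 0.05) between successive time points of each season, with intervals in days after veraison on the x axis and numbers of genes on the y axis (rose above 0, fell below 0). The tallest bars are the 2232 genes that fell from day -9 to day 0 of 2012 and the 1835 that fell from day -13 to day -6 of 2013.

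The RPKM values came in 2 forms, which followed the season closely and, within 2013, fell unequally on the thinning arms. Of 9114 genes that held at least 5 RPKM in the mean of every 2012 cell, 121 libraries listed at most 14 under 0.5 RPKM, and 83 libraries listed 31 to 50. The 83 libraries of the second form were all 72 of 2014 and 11 of 2013: replicate 2 of the 75% arm on days -20 and -6, the 3 replicates of the 75% arm on day 36 and all 6 libraries of day 43. In each cell that held both forms, the second-form library also had the highest ripening score, so form and stage were not told apart there. Within these cells, 406 genes differed at least 2-fold, 405 of them lower in the second form, and these are called form-dependent. Of the 406, 184 had IDs that start with VIT_00s, 45.3%, against 7.92% of all tested genes.

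**Figure D3:**
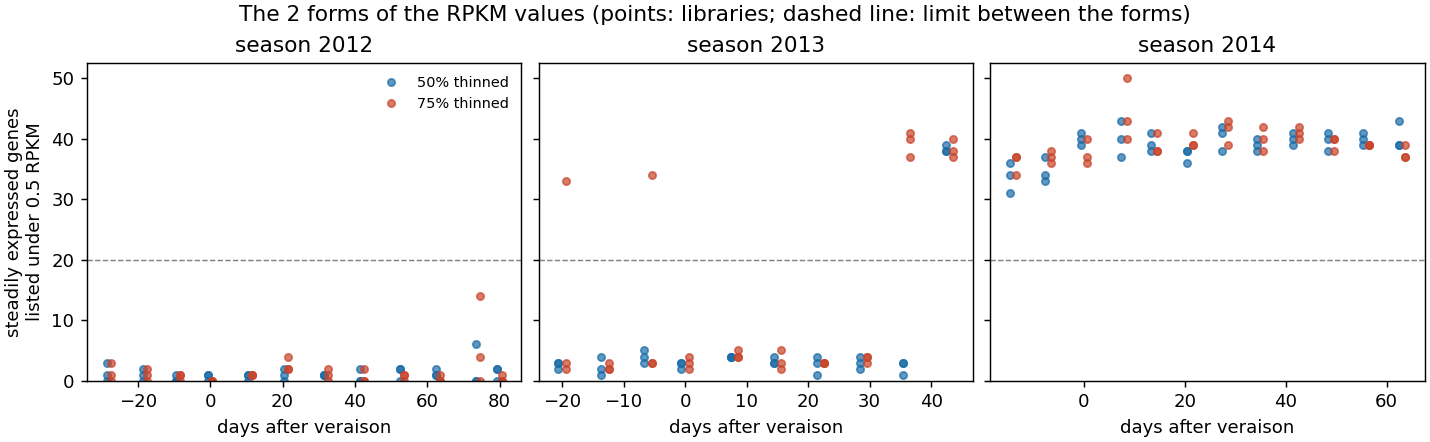
Number of steadily expressed genes listed under 0.5 RPKM in each library (y axis) against days after veraison (x axis) in the seasons 2012, 2013 and 2014, with the limit between the forms as a dashed line. All libraries of 2014 lie at 31 or above and all of 2012 at 14 or below, and 11 libraries of 2013 lie with those of 2014.

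Ripe berries of the 3 seasons were compared at the last 2 time points, days 74 and 80 of 2012, 36 and 43 of 2013 and 56 and 63 of 2014. Between 2012 and 2013, 1418 genes differed at least 2-fold, 720 higher and 698 lower in 2013. Between 2012 and 2014, 875 differed, 343 higher and 532 lower in 2014, and between 2013 and 2014, 198 differed, 80 higher and 118 lower in 2014. The sign was the same in both thinning arms for 1416 of the 1418, 874 of the 875 and 179 of the 198 genes, which were called on the mean of the arms. Against 2012, 200 of the 698 genes lower in 2013 and 241 of the 532 lower in 2014 were form-dependent, and 0 of the 720 and 343 higher ones. With the form as a covariate, 604 genes were higher and 209 lower in 2014 than in 2012, and 964 and 439 in 2013 than in 2012, and with second-form libraries alone 103 genes differed between 2014 and 2013. The covariate rests on berries before veraison, where replicate 2 of the 75% arm on days -20 and -6 of 2013 held the second form. Whether its estimate holds for ripe berries was not tested. Season cannot be told apart from the time since veraison at these points or from any batch of harvest, extraction or sequencing.

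Sugar content was slightly higher at 75% thinning in 2013, and no season's difference passed the test after adjustment. Sugar at 75% minus 50% thinning was 0.01 g/100 ml in 2012, 0.54 in 2013 and 0.16 in 2014 (36, 30 and 36 libraries per arm). The SD of these differences over time points was 1.49, 1.16 and 1.21. Permutation of the labels within time points (two-sided, 100000 resamples) gave p = 0.984, 0.0424 and 0.607, adjusted over the 6 tests of sugar and score to 0.984, 0.202 and 0.911. The 75% arm was higher at 5 of 12, 8 of 10 and 8 of 12 time points. An exact test on the 3 against 3 means per replicate number, which cannot go below 0.1, gave 1.0, 0.1 and 0.7. The difference did not pass a test between seasons (permutation p = 0.548).

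The ripening score of the 75% arm was ahead around veraison of 2014, and no season's mean difference passed the test. The difference was -0.01 in 2012, 0.09 in 2013 and 0.24 in 2014 at 75% minus 50% thinning, with SDs over time points of 0.24, 0.16 and 0.65. Permutation within time points gave p = 0.913, 0.277 and 0.0674, adjusted to 0.984, 0.555 and 0.202. In 2014 the 75% arm differed by -0.02 on day -14 (exact p = 0.9), was ahead by 1.91 on day -7 and 1.26 on day 0, and differed by at most 0.16 in either direction from day 8 on. With 3 pools against 3, the exact p on days -7 and 0 was 0.1 and 0.3, and 0.1 is the smallest possible. The season differences did not pass a test between seasons (permutation p = 0.231).

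Averaged over the 3 seasons and all time points, 168 genes differed between the thinning intensities in limma, 35 higher and 133 lower at 75%, with small differences. The median log2 difference was 0.10 among the higher genes and -0.10 among the lower, and 0 genes differed 1.5-fold. Across all genes tested, the thinning differences of 2012 and 2013, 2012 and 2014, and 2013 and 2014 had Pearson's r = 0.102, 0.157 and 0.140, and 14, 8 and 12 of 100 splits of the libraries, the real one included, gave an r at least as high. Of the 133 lower at 75%, 67 fell at onset and 35 fell late, while 3 rose at onset. Of the 35 higher at 75%, 16 rose late and 6 at onset, while 1 fell at onset. VIT_12s0057g01110 was at 13.1 RPKM ± 20.9 (SD, n = 102 libraries over all stages) at 75% and 10.4 ± 18.2 (n = 102) at 50%, a log2 difference of 0.22 (SE 0.06, limma adjusted p = 0.0414). VIT_01s0011g02710 was at 265 RPKM ± 340 and 304 ± 379, a log2 difference of -0.28 (SE 0.08, limma adjusted p = 0.0451). With the form as a covariate 25 genes were called, 6 higher and 19 lower, of which 24 were among the 168, and neither named gene was called. Their log2 differences in that fit were 0.20 (SE 0.06, limma adjusted p = 0.132) and -0.28 (SE 0.08, adjusted p = 0.12). On means per replicate number, 3 against 3 in each season, limma called 0 genes, and without replicate 1, 2 or 3 it called 0, 0 and 48, against 3558 at an unadjusted p under 0.05 with all libraries. Without replicate 2 of the 75% arm of 2013, which holds the libraries of the second form on days -20 and -6, limma called 0. With median ratio scaling 118 genes were higher and 238 lower, and with quantile normalization 53 and 74. Among the 65 libraries whose year tag goes with the season, which cover 11 time points, the balance turned, to 121 higher and 45 lower.

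Of the 25 genes called with the form as a covariate, 19 were lower at 75%, and of these 14 fell at onset and 7 fell late. Of the 6 higher, 5 rose late and 2 rose at onset. Their log2 differences lay between -0.18 and 0.18.

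Single seasons gave few genes once the forms were taken into account. In 2012, VIT_18s0072g00850 was lower at 75% by a log2 difference of -2.25 (SE 0.40, limma adjusted p = 0.00167), and it is listed at 0 in at least 1 library whose other replicates hold at least 5 RPKM; it was not called without replicate 2 or 3. In 2014, VIT_01s0137g00430, VIT_19s0014g01640 and VIT_07s0151g00280 were higher, by 0.38 (SE 0.08), 0.19 (SE 0.04) and 0.17 (SE 0.03), and VIT_13s0067g00080 was lower, at -0.14 (SE 0.03), each with a limma adjusted p of 0.0175. These single-season genes are named because they are few and were chosen after their values were seen. Without replicate 1, 2 or 3 the 2014 count was 0, 32 and 1, and median ratio scaling gave 19 higher and 11 lower genes. In 2013, 1 gene was higher and 196 were lower, with a median log2 difference of -0.35. Among libraries whose year tag goes with the season the balance turned, to 181 higher and 59 lower. Of these 196, 161 were form-dependent, and second-form libraries made up 8 of the 30 libraries of the 75% arm and 3 of the 30 of the 50% arm. With the form as a covariate, or without the 8 libraries left out for mixed form, limma called 0 genes in 2013, while 1157 genes had an unadjusted p under 0.05 in the fit without it. The covariate also takes up the arm difference of day 36, where form and arm coincide. Without replicate 2 of the 75% arm, limma also called 0 genes in 2013. The moderated F test found 0 genes whose thinning difference depended on the season in limma, with 1029 at an unadjusted p under 0.05, and it called 74 genes when sugar was a covariate.

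Thinning was also compared in 4 windows of development. On day 0, averaged over seasons, 350 genes were higher and 1195 lower at 75%. Of the 716 that also belonged to the onset program, 99.7% had moved in the direction of ripening. In early ripening 222 genes were higher and 653 lower, with 95.4% of 175 onset genes in the direction of ripening. Onset genes were 175 of these 875 calls, against 22.4% of all genes tested. In both windows most calls were lower, and most onset genes fell, which alone favours such agreement. No baseline for it was computed. Green berries gave 19 genes, all lower, and the last 2 time points gave 132, of which 99 were form-dependent; with the form as a covariate the balance turned, to 12 higher and 5 lower. These windows were chosen after seeing the data. Without the 2014 season the veraison window gave 11 genes, without 2012 823 and without 2013 2393. It was 190 without replicate 3 and 309 without replicate 2, and the early ripening count was 26, 44 and 629 without replicate 1, 2 and 3. Without replicate 2 the balance in early ripening turned, to 30 higher and 14 lower. In green berries the direction turned without replicate 1, with 93 genes higher and 20 lower; without replicate 2 it was 2 and 2, and without replicate 3 it was 21 and 44. The last 2 time points gave 51, 168 and 5 genes without replicate 1, 2 and 3. Median ratio scaling gave 704 higher and 1047 lower genes at veraison, and 466 and 603 in early ripening. Quantile normalization gave 531 higher and 563 lower genes at veraison, and 286 and 427 in early ripening. The test of the difference between stages, after minus before veraison, called 2 genes in limma, with 1308 at an unadjusted p under 0.05.

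The 3 time points with the most calls were days 0, 8 and 28 of 2014. On day -7 of that season, with fewer calls, 418 genes were higher and 69 lower at 75%, and 99.7% of the 331 onset genes among them moved in the direction of ripening. On day 0, 265 were higher and 1870 lower, with 97.7% of 1123 onset genes in that direction, and on day 8, 218 were higher and 1866 lower, with 88.3% of 171. On day 28 the balance was the other way, with 1003 higher and 80 lower and 26.3% of 95 onset genes in the direction of ripening. In 2013, day 36 gave 695 genes, all lower at 75%, and on that day the arms held different forms. Of the 34 season time points, 6 gave 0 genes in limma, and the sum of genes at an unadjusted p under 0.05 over all of them was 43943. Single libraries moved these counts. In 2014, day -7 gave 303 genes without replicate 2 of the 50% arm, and 84, 1262 and 245 without replicate 1, 2 and 3 of the 75% arm. Day 0 gave 1058 without replicate 2 of the 50% arm and 888 without replicate 3 of the 75% arm. Day 8 gave 865 without replicate 3 of either arm, and 3680 and 988 without replicate 1 and 2 of the 75% arm. Day 28 gave 441, 2968 and 51 without replicate 1, 2 and 3 of the 50% arm, and 325, 129 and 141 without those of the 75% arm.

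**Figure D4:**
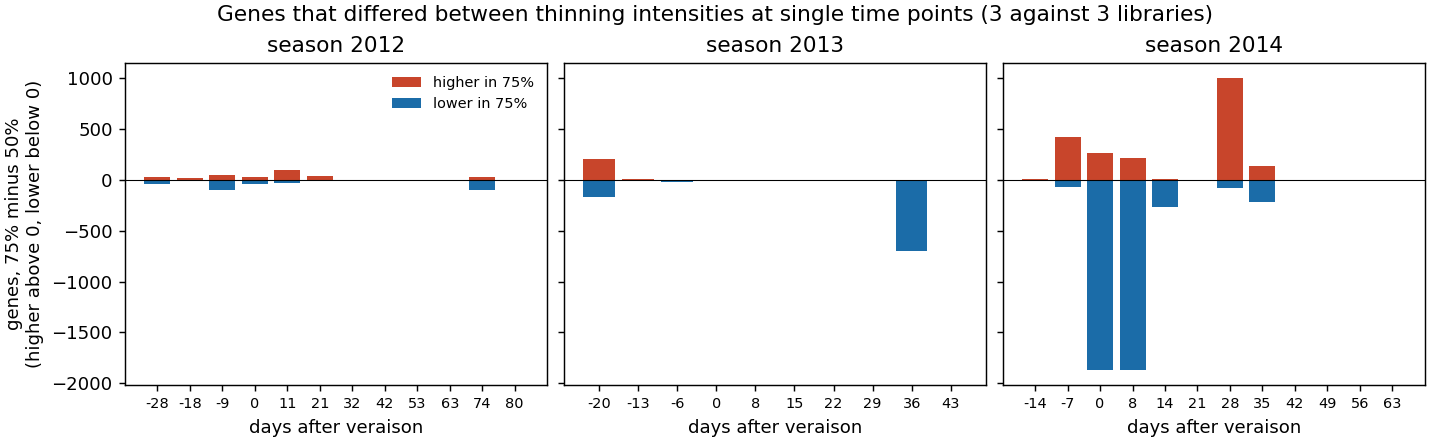
Genes higher (above 0) or lower (below 0) at 75% than at 50% thinning on each sampling day (x axis, days after veraison) of the seasons 2012, 2013 and 2014, from limma with 3 libraries per arm. The tallest bars are the 1870 genes lower on day 0 and the 1866 lower on day 8 of 2014.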

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

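The tests reported in this part were chosen after the results were seen, apart from those named next. The comparison of stages and the thinning tests within seasons, between seasons and at single time points were planned. The days singled out here were chosen afterwards. The thinning difference changed between stages, in a test of the difference itself, for 2 genes: after minus before veraison, VIT_06s0009g02730 and VIT_16s0022g02370 rose at 75% relative to 50% thinning, by 0.15 (SE 0.03) and 0.18 (SE 0.04) on the log2 scale, both with a limma adjusted p of 0.0452. They average 0.171 and 0.463 RPKM, and both were chosen by that test. Without replicate 1 the test called 5 genes that rose and 47 that fell, so the direction turned; without replicate 2 it called 2 and 7, and without replicate 3 15 and 7. Of 100 splits of the libraries within time points, 80 gave at least as many genes and the highest other split gave 562, so chance cannot be excluded.

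In 2013, 196 genes were lower at 75% thinning, and mixed forms of the RPKM values are a candidate explanation. On day 36, when all 3 libraries of the 75% arm and none of the 50% arm held the second form, the median log2 difference of these genes was -1.94. Over the 7 time points with 1 form in both arms it was -0.0193, with quartiles of -0.0543 and 0.0117, which argues against a thinning difference throughout the season. A small thinning difference in these genes stays open, because they were chosen in a fit that includes those time points, so a median slightly below 0 there decides nothing. Of 100 splits, 4 gave at least the 197 genes of 2013 and the highest other gave 210. That share was not adjusted for the number of split tests, so this count does not exclude chance. Forms that fall unequally on the arms are not excluded by it either.

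The forms themselves argue against a season or stage effect as their whole cause, because replicate 2 of the 75% arm on days -20 and -6 of 2013 listed at least 33 steadily expressed genes under 0.5 RPKM and the other replicates of the same cells at most 3. Random loss of reads at lower depth would strike different genes in each library, whereas 20 genes were under the limit in every one of the 83 second-form libraries. Of all such values, 76.3% lay in 30 genes that were low in at least 90% of these libraries. This is consistent with a technical difference in preparation or processing between libraries, and preparation and processing were not separated. The 406 form-dependent genes compare with 168 in the highest of the other 8 choices of the odd replicate, and 9 choices are too few for a share under 0.05.

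The thinning difference on day 0 of 2014 is in the direction of ripening, where 97.7% of the 1123 onset genes among the calls moved that way, and a later stage of the 75% berries that were sampled may account for it. Whether a later stage also accounts for day 8 stays open. There 171 of 2084 calls were onset genes, against 22.4% of all genes tested, so the calls were not enriched in onset genes. Of these 171, 88.3% moved in that direction. The ripening score on day 8 was 3.98 ± 0.36 (SD, n = 3) at 50% and 3.99 ± 0.55 at 75%, a difference of 0.00686. Sugar on that day was 11.18 ± 1.01 at 50% and 12.15 ± 0.44 at 75% (exact test, p = 0.2). These spreads are too wide to decide it. Of the libraries of day 0 of 2014, 0 held the first form, which excludes mixed forms, and 832 of the 2135 calls or more were still called whichever library was left out, which argues against a single pool as the whole cause, although over all seasons the veraison count fell from 1545 to 190 without replicate 3. Whether thinning, the position of the rows or the choice of berries set the stage stays open, and thinning was not shown to differ in effect between seasons. Of the 10 splits of the 6 libraries, 1 gave as many genes as the real one on day 0, where the highest other gave 1789, and 2 did on day 8, where it gave 3237, and on day -7, where it gave 1080 beside a real count of 487; 10 splits are too few for a share under 0.05.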

How the results depend on the processing

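Alternatives that concern the forms, genes with an implausible 0, blocks at each time point, windows of thinning, separate early-ripening libraries, single libraries and seasons left out at veraison were chosen after seeing the data. Read depth is unknown, so no limit from depth was computed. For the changes listed here the cause was not tested unless stated. Of 382 counts of genes under an alternative, 255 stayed within 1.5 times the main count and 127 did not. Of 69 alternatives of sugar and score, 44 stayed the same, 8 lost and 5 gained an unadjusted p under 0.05 and 12 reversed. The overlap of the onset and late lists was taken again with separate early-ripening libraries, and all 4 classes stayed within 1.5 times the main count. The camera tests were not run, since no gene names matched.

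Ripening onset, late ripening, the harvest comparisons and the 3 leading intervals moved by over 1.5 times only as follows. A pseudocount of 0.1 gave 5188 genes for late ripening, 2912, 1957 and 637 for harvest 2013 minus 2012, 2014 minus 2012 and 2014 minus 2013, and 4568, 3893 and 3809 for the intervals of 2012, 2013 and 2014. Without a fold threshold, which admits smaller changes by construction, the counts were 18372 at onset, 17701 late and 13165, 11537 and 6639 at harvest. Second-form libraries alone gave 103 genes for harvest 2014 minus 2013.

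The mean thinning difference (168 genes) went to 100 with a pseudocount of 0.1, 85 with no filter, 356 with median ratio scaling, 0 on means per replicate number, 0 at 1.5-fold, 25 with the form covariate, 108 without form-dependent genes and 28 without the mixed-form libraries of 2013. With the year tag the count was 166, but 121 of these were higher and 45 lower; in 2013 it was 240, with 181 higher and 59 lower. Leaving out replicates or single season by arm sets gave 0 to 368. For 2012 (1 gene), median ratio scaling and quantile normalization gave 2, and replicate means, a separate fit, the year tag and leaving out genes with an implausible 0 gave 0; leave-out counts were 0 to 9. For 2013 (197), replicate means gave 28, a separate fit 0, 1.5-fold 33, the form covariate 0, leaving out form-dependent genes 6 and leaving out mixed-form libraries 0, and leave-out counts were 0, without replicate 2 of the 75% arm, to 318. For 2014 (4), the counts were 30 with median ratio scaling, 22 with quantile normalization, 2 with the year tag and 0 with replicate means, a separate fit or 1.5-fold, and 0 to 125 with sets left out. The test between seasons (0) gave 74 genes with sugar as a covariate and 104 with the year tag. After minus before veraison (2) gave 0 with a pseudocount of 0.1, the stricter filter or either block, 10 with no filter, 4 with median ratio scaling, 1 with quantile normalization and 9 to 52 with a replicate left out. The sum over single time points (8170) was 5433 with quantile normalization, 419 with the year tag, which keeps 11 of 34 time points, and 3348 to 7703 with a replicate left out.

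Of the windows, green berries (19) gave 1 with a pseudocount of 0.1, 77 with no filter, 3 with the stricter filter, 5 with the form covariate and 4 to 113 with a replicate left out. Veraison (1545) gave 823, 2393 and 11 without 2012, 2013 and 2014, and 190 to 1544 without a replicate. Early ripening (875) gave 26 to 629 without a replicate, and the last 2 time points (132) gave 17 with the form covariate, 12 higher and 5 lower, 15 without form-dependent genes and 5 to 168 without a replicate. Leaving out 1 of the 6 libraries gave 84 to 1262 genes on day -7 of 2014, 888 to 2916 on day 0, 865 to 3680 on day 8 and 51 to 2968 on day 28.

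Sugar in 2013 (0.54 g/100 ml) stayed positive, between 0.32 and 0.71, with replicates left out, and the unadjusted p stayed under 0.05 only without replicate 1 of the 50% arm (0.60) and replicate 2 of the 75% arm (0.71). Sugar in 2012 ranged from -0.29 to 0.40 and in 2014 from -0.075 to 0.31. The score in 2012 was 0.000586 with 500 genes per direction and -0.16 to 0.13 with replicates left out, in 2013 it was -0.0455 to 0.21, and in 2014 it was 0.185 with 500 genes, where the unadjusted p fell under 0.05, and 0.14 to 0.33, where it did so without replicate 1, and without replicate 1 or 2 of the 75% arm; in 2013 it did so without replicate 3. None of these passed a test in the main setting after adjustment.

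Same-numbered libraries of the 2 arms at a time point had residuals correlated at 0.0733 on average, against -0.0357 for other numbers. By season the values were 0.131 against -0.0612 in 2012, -0.00503 against 0.00274 in 2013 and 0.0808 against -0.0422 in 2014. Of 102 pairs 35 were over 0.1, and 83 libraries correlated best with their own number. Since the labels give no shared origin and not every pair was over 0.1, the libraries were not treated as paired; the 2012 and 2014 values are a hint from the data. With the number as a replicate block at each time point, 385 genes were called for the mean thinning difference and 1416 in early ripening, and sugar in 2013 (0.544) had a p of 0.064. The block within season left the mean thinning count at 172.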

Other observations

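The tests in this part were chosen after the data were seen, except that the counts of genes from ripening, harvest and thinning that the splits concern were planned, other than those of windows, intervals and the form covariate. Fewer genes reached 1 RPKM after the onset of ripening. Green berries of 2012 had 17410 ± 226 genes at 1 RPKM or more (mean ± SD, n = 18 libraries) and berries of days 8 to 22 had 15820 ± 74.5 (n = 12); in 2013 the values were 17380 ± 410 and 16340 ± 118 (n = 18 each) and in 2014 17270 ± 158 (n = 12) and 15800 ± 165 (n = 18). Each drop had a permutation p of 2e-05, the smallest these two-sided permutations can give, adjusted over 12 tests to 3.43e-05. Over the same step the share of all RPKM in the 10 highest genes of a library went from 12.7% ± 2.71 to 24.7% ± 2.56 in 2012, from 15.5% ± 1.87 to 21.5% ± 2.14 in 2013 and from 14.3% ± 1.53 to 23.3% ± 1.11 in 2014, with the same p. All permutations of this paragraph moved single libraries, while the libraries of a window came from only a few sampling days. Their p-values therefore measure the spread between libraries and not between days. From days 8 to 22 to the last 2 time points the number of genes at 1 RPKM or more changed by 83.8 in 2012 (permutation p = 0.182, adjusted 0.199), by -433 in 2013 (p = 2e-05, adjusted 3.43e-05) and by 124.5 in 2014 (p = 0.0338, adjusted 0.0406). The form of the values moved with the drop of 2013: the 18 libraries of days 8 to 22 held the first form, and 9 of the 12 libraries of the last 2 time points held the second. On day 36 of 2013 the 3 first-form libraries, of the 50% arm, had 16105, 16082 and 16264 such genes and the 3 second-form libraries, of the 75% arm, had 16003, 15855 and 15783. The drop of 2013 was not told apart from the form. The share of the 10 highest genes changed over that step by -5.03 points in 2012 (adjusted p = 0.00187), 0.507 in 2013 (0.517) and -3.29 in 2014 (0.00015). RPKM is a share of all reads, so a larger share for a few genes lowers the RPKM of the rest, and a loss of expression was not told apart from this.

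Pools of berries of 1 cell may differ in stage most while the ripening genes move fastest. In cells of days -9 to 0, the SD between replicates was 1.72 ± 0.20 (SD, n = 12 cells) times as large in onset genes as in other genes, against 1.38 ± 0.14 (n = 56 cells) at all other times (permutation p = 2e-05). The SD of the other genes was 0.242 ± 0.028 in these cells and 0.257 ± 0.046 elsewhere (permutation p = 0.31). The ratio was higher near veraison in each season, with exact p = 0.000188 in 2012 (4 against 20 cells), 0.0429 in 2013 (4 against 16) and 0.0128 in 2014 (4 against 20). Some earlier green cells were also high. At 50% and 75% the ratio was 1.65 and 1.63 on day -14 of 2014. It was 1.63 and 1.32 on day -20 and 1.49 and 1.77 on day -13 of 2013. On days -28 and -18 of 2012 it lay between 1.24 and 1.54. Whether the higher ratio is particular to days -9 to 0 among berries before veraison was not tested. The SD of the onset genes alone was 0.458 against 0.38 in 2012 (exact p = 0.0847), 0.356 against 0.316 in 2013 (exact p = 0.228) and 0.441 against 0.354 in 2014 (exact p = 0.0213). In 2012 the SD of the other genes was lower near veraison, 0.25 against 0.293 (exact p = 0.0495), which adds to the ratio; it was 0.217 against 0.22 in 2013 (exact p = 0.826) and 0.26 against 0.249 in 2014 (exact p = 0.56).

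The differences between arms were also expressed as days along the mean course of the season. The 75% arm was ahead in score by -0.091 days in 2012, 0.279 in 2013 and 2.78 in 2014 (permutation within time points, two-sided, p = 0.943, 0.626 and 0.0398, adjusted over 6 tests to 0.943, 0.788 and 0.216). In sugar it was ahead by 0.692, 1.08 and 1.28 days (permutation p = 0.657, 0.108 and 0.0757, adjusted to 0.788, 0.216 and 0.216). Bootstrap 95% intervals excluded 0 for the score in 2014 (0.965 to 4.42) and for sugar in 2013 (0.0911 to 2.18) and 2014 (0.196 to 2.29), but they draw from 3 libraries per cell, and 0 of the 6 differences passed the permutation test after adjustment.

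Libraries with more sugar than the other replicates of their cell may be ahead in expression, and a positive relation with the score was found in part of the season. Over veraison and days 8 to 22, deviations of sugar and of ripening score from the cell mean had Pearson's r = 0.403 (permutation p = 3e-05, adjusted over 7 sets 0.00021) and Spearman's rho = 0.513 (p = 5e-05, adjusted 0.00035) in 66 libraries, and r = 0.414 without the 2 libraries farthest from the median of sugar. Within seasons, r in this window was 0.32 (p = 0.00652, adjusted over 3 seasons 0.00978) in 18 libraries of 2012, 0.242 (p = 0.328, adjusted 0.328) in 24 of 2013 and 0.606 (p = 0.00112, adjusted 0.00336) in 24 of 2014, and rho was 0.536 (p = 0.00964, adjusted 0.0145), 0.238 (p = 0.336, adjusted 0.336) and 0.646 (p = 0.0028, adjusted 0.0084). Without the farthest 2, r was 0.32, 0.238 and 0.636, so the relation did not pass the test within 2013. In the 90 libraries after day 22 r was -0.384 (p = 0.0152, adjusted 0.0532) and rho -0.272 (p = 0.0452, adjusted 0.158), with r = -0.28 without the farthest 2. The positive relation of the earlier window was not found there. The score itself fell late, from 5.96 on day 42 to 5.31 on day 74 in the 50% thinned berries of 2012. A negative r there therefore does not decide whether libraries with more sugar were ahead. Before veraison r was 0.556 (p = 0.0479, adjusted 0.0839) and rho 0.246 (p = 0.221, adjusted 0.277) in 48 libraries, and r fell to 0.337 without the farthest 2. Over all libraries r was 0.102 (p = 0.046, adjusted 0.0839) and rho 0.116 (p = 0.129, adjusted 0.274), with r = 0.121 without the farthest 2; per season r was 0.0473, 0.178 and 0.176 in 2012, 2013 and 2014, with p = 0.512, 0.0789 and 0.0911, adjusted to 0.512, 0.106 and 0.106, and rho was 0.0648, 0.152 and 0.194, with adjusted p of 0.604, 0.277 and 0.274.

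Splits of the libraries into groups of the same sizes, 100 in each case with the real one, show which counts exceed chance groupings. For ripening onset (4654) 1 split, the real one, was as large and the highest other gave 0; for late ripening (2901) it was also 1, with 114. For harvest 2013 minus 2012 (1418), 2014 minus 2012 (875) and 2014 minus 2013 (198), 1, 1 and 3 splits were as large and the highest others gave 309, 234 and 304. The leading intervals of 2012 (2895), 2013 (2476) and 2014 (1964) stood alone at 1 split each, with 2118, 1465 and 1151 as the highest others. No other split reached these counts, except for harvest 2014 minus 2013, where other splits called more. The share of splits was not adjusted for the number of such tests. For onset and late ripening, stage labels were shuffled over whole seasons. This adds the ripening changes to the spread and can lower the counts of the other splits. The leading intervals were chosen as the largest of each season, with no allowance for that choice, so chance is not excluded for them. Among thinning results, the mean of seasons with the form covariate (25 genes) and without it (168) had 1 split as large, and the highest other gave 1. Splits of single libraries thus did not reach these counts. They do not test chance differences between the vines or rows of the arms, so chance is not excluded at that level. For veraison (1545) 3 splits were as large and the highest other gave 2549, and for early ripening (875) it was 1 split and 858. Chance is not excluded for these 2 windows, which were chosen after seeing the data, with no allowance for that choice. Veraison gave 11 genes without the 2014 season, and early ripening 26 and 44 without replicate 1 and 2. These splits treat libraries as independent. For the mean of seasons, means per replicate number gave 0 genes, and a fit with a correlation among libraries of 1 season, arm and replicate number, estimated at 7.8e-05, gave 165, 35 higher and 130 lower. The labels do not say whether a replicate number marks the same vines at every time point.

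Chance cannot be excluded by such splits for thinning in 2012 (1 gene, 24 splits as large, highest other 3286), in 2014 (4 genes, 5 splits, 1932), in green berries (19 genes, 60 splits, 1117), at the last 2 time points (132 genes, 18 splits, 1667) and for the sum over single time points (8170, 21 splits, 17060). Between seasons the real count was 0, so all 100 splits were as large by construction and decide nothing. The highest other split there gave 530. Splits that call many times the real count where the real count is small point to a structure of the samples, and what that structure is was not tested. On day 28 of 2014 (1083 genes) and day 36 of 2013 (695) the highest of the 9 other splits gave 251 and 1, and 10 splits are too few for a share under 0.05. The mean thinning difference correlated with the onset change across genes at r = 0.325, and 4 of 100 splits gave a correlation as high, the highest other being 0.401.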
